A study of Mus musculus and Sus scrofa with 12 samples.

How the data were processed

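The study profiled 3 histone modifications in embryonic forelimbs of wild-type mice at E11.5 and pigs at day 23 of gestation. H3K4me3 marks promoters, H3K27ac marks active promoters and enhancers, and H3K4me1 marks enhancers and the flanks of promoters. The assay was ChIPmentation, a form of chromatin immunoprecipitation in which a transposase inserts the sequencing adapters into chromatin while it is bound to the antibody. Per the series' design text, chromatin was fixed with 1% formaldehyde, 1 µg of antibody was used, and forelimbs of littermates served as biological replicates that were each divided into technical replicates. The labels list 12 samples, with 2 for each of the 6 combinations of species and modification. For pig H3K4me1 the design text states a single biological replicate with technical replicates, whereas the labels name 2 samples, so the sources differ on whether the pig H3K4me1 list rests on 1 or 2 biological replicates.

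The authors deposited 6 lists of peak positions, 1 per species and modification, which hold chromosome, start and end with no score, signal or p-value. Per the design text, reads were 50 bp after cropping, mouse reads were aligned to GRCm38/mm10 and pig reads to Sscrofa11.1/susScr11, and peaks were called in a broad mode with an irreproducible discovery rate below 0.01. Pig H3K27ac and H3K4me3 libraries were sequenced at 50 bp, while pig H3K4me1 and all mouse libraries were sequenced at 100 bp and cropped, so read length at sequencing went with species for H3K27ac and H3K4me3 only. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, Bowtie2 2.3.5, SAMtools 1.9 and deepTools 3.5 were used. The peak caller is not given in the sources used here. Each deposited list is a consensus over replicates, so no spread between replicates could be computed, the depth per sample is unknown, and every p-value below compares lists or genes, not animals.

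Peaks were read with Python 3.11.15 and numpy 2.4.6 and placed on the NCBI RefSeq annotation of the same assemblies, which held 21774 mouse and 20609 pig protein-coding genes. A gene counted as marked when a peak overlapped, by 1 bp or more, the window of 1 kb on each side of any of its annotated transcription start sites (TSSs). Distal H3K27ac peaks were those that overlapped neither such a window around any annotated TSS nor an H3K4me3 peak, and each was assigned to the gene with the nearest coding TSS within 500 kb. The territory of a gene is the distance between the coding TSSs on its 2 sides. Orthologs were taken as the 14948 genes with the same symbol, letter case ignored, and 1 record in each annotation. Mouse peaks on unplaced scaffolds, 17 for H3K4me3, 15 for H3K27ac and 4 for H3K4me1, were not used in the comparisons. The overlap of modifications was computed on assembled chromosomes only, which held 18331 of the pig H3K4me3 peaks, 27217 of H3K27ac and 102421 of H3K4me1.

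The overlap of modifications within a species was compared with 1000 circular shifts of the second list along each chromosome, whose smallest two-sided p is 0.002. A set of 18 gene lists was fixed before the data were examined, with 9 lists from limb development, 1 of housekeeping genes, 5 for other cell types that a dissected forelimb could hold, and 3 for tissues outside the limb. Members of each list were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 108 tests. Marking of orthologs in the 2 species was compared by Fisher's exact test, and list members marked in 1 species only by an exact McNemar test and by Fisher's exact test against all other such orthologs, over 54 tests. The median number of distal H3K27ac peaks per gene of a list was set against 10000 random lists of the same size, matched on the quintile of territory, over 36 tests. Across orthologs, numbers of distal peaks were compared by a partial Spearman correlation on territory with 10000 permutations. Adjusted p-values under 0.05 counted as calls. Intervals of shares are 95% Wilson intervals and cover counting error only. These tests were run in scipy 1.17.1.

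Sequences of distal mouse H3K27ac peaks were searched with blastn 2.17.0 against pig peaks of H3K27ac or H3K4me1, with repeats masked and an E value of 1e-10 or lower. Controls were mouse regions of the same width outside all peaks and TSS windows and at a like distance from a TSS. A seeded sample of 1500 peaks and 1500 controls was also searched against the whole pig genome. Each test except that of the sequence match was first run on simulated data. For marking at the TSS, 3.6% of simulated lists without an effect reached p under 0.05. For distal peaks near genes with long territories, 5% did when random lists were matched, against 83.3% when they were not. These simulated lists came from nearly the same genes as the top quintile of territory on which they were matched. The 5% therefore could not test how matching works within that quintile.

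Named genes were chosen by a rule fixed before the data were examined. It takes the 2 to 4 members of each list with the most distal H3K27ac peaks, the members of the hedgehog, FGF, BMP, posterior Hox and limb mesenchyme lists marked by H3K27ac or H3K4me3 in 1 species only, the 10 genes per species with the most distal H3K27ac peaks, the 10 with the widest H3K4me3 peak, and the 5 orthologs per direction with the largest difference in distal peaks. Other limb genes marked in 1 species only were named after their values were seen. Alternatives tried were the wider upper 50% of each list, a 2.5 kb TSS window, the 5' end of the gene only, equal numbers of peaks in both species, autosomes only, other definitions and assignments of distal peaks, random lists without matching, and a stricter sequence match. A background of orthologs only, territory in 20 bins, regions without exons and matches near the same gene were added after the data were examined.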

Results

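The deposited data describe where 3 histone modifications were called in forelimbs of mouse embryos at E11.5 and pig embryos at day 23. Each of the 6 peak lists is a consensus, for which the labels give 2 samples per species and modification. For pig H3K4me1 the design text states a single biological replicate. The mouse lists held 18353 H3K4me3, 20875 H3K27ac and 69962 H3K4me1 peaks, and the pig lists held 18713, 27566 and 103373. Peaks covered 2.18%, 2.27% and 8.74% of the mouse genome and 1.29%, 1.36% and 12.8% of the pig genome. No value per replicate or per peak was given, so differences between species could not be set against a spread between animals.

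The first question was how the 3 modifications lay along the genome of each species. H3K4me3 lay mostly at genes' start sites: 81.0% of mouse peaks (95% interval 80.5 to 81.6) and 72.1% of pig peaks (71.5 to 72.8) overlapped the 1 kb around a TSS. H3K27ac lay there in 46.8% and 35.7% of peaks, and H3K4me1 in 25.5% and 16.5%. At coding genes the commonest state was all 3 modifications together, at 6865 mouse genes (31.5%) and 7196 pig genes (34.9%). H3K4me3 without H3K27ac was found with H3K4me1 at 3782 mouse and 3328 pig genes and alone at 1557 and 759, whereas H3K27ac without H3K4me3 marked 119 and 243 genes with H3K4me1 and 130 and 90 genes alone.

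Every pair of modifications overlapped more than shifted lists did. In mouse, 50.9% of H3K4me3 peaks overlapped H3K27ac against 5.08% after shifting, a 10.0-fold excess, and in pig 56.7% did against 3.55%, a 16.0-fold excess. H3K27ac peaks overlapped H3K4me1 in 63.5% of cases in mouse and 70.7% in pig, at 3.70-fold and 3.62-fold over shifted lists. In the stricter count, where at least 50% of the first peak was covered, the excess of H3K27ac peaks on H3K4me3 rose from 10.0-fold to 18.5-fold in mouse and from 16.1-fold to 27.4-fold in pig. In the same count the excess in pig fell from 3.46-fold to 2.70-fold for H3K4me3 peaks on H3K4me1 and from 3.71-fold to 2.53-fold for H3K4me1 peaks on H3K4me3. All 12 ordered pairs had an adjusted permutation p of 0.002, the smallest that 1000 shifts can give, two-sided. Of the 10095 distal H3K27ac peaks in mouse, 48.1% (47.1 to 49.1) overlapped an H3K4me1 peak, and of the 15795 in pig 72.2% did (71.5 to 72.9). Conversely, 9.72% of distal H3K4me1 peaks in mouse and 12.2% in pig overlapped H3K27ac.

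Peaks were narrower in pig for H3K4me3 and H3K27ac. The median width was 3308 bp in mouse and 1679 bp in pig for H3K4me3, a ratio of 0.508, and 2928 bp and 1164 bp for H3K27ac, a ratio of 0.398. For H3K4me1 the medians were 3392 bp and 3033 bp, a ratio of 0.894. Pig H3K4me3 and H3K27ac libraries were also the only ones sequenced at 50 bp.

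**Figure D1:**
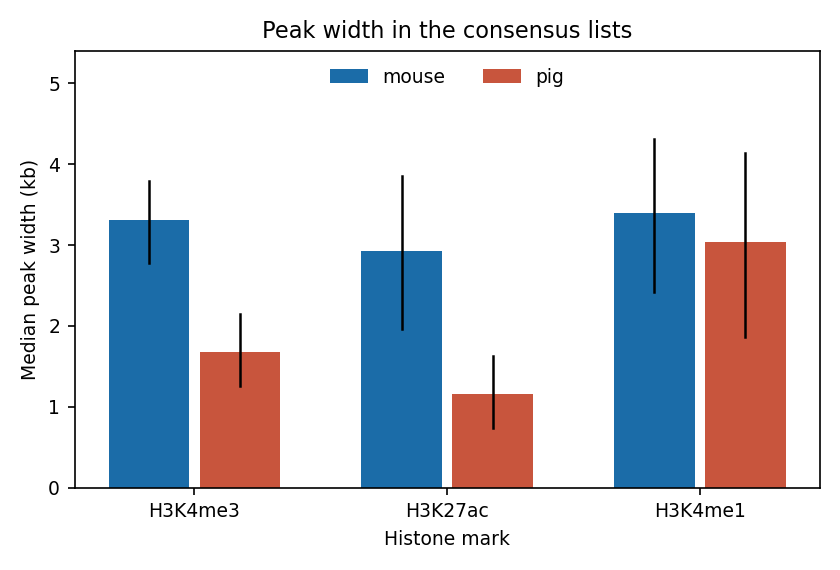
Median peak width in kb (bars, y axis) for each histone mark (x axis) in mouse (blue) and pig (red), with black lines from the lower to the upper quartile over peaks. Pig medians were 0.508 of the mouse median for H3K4me3, 0.398 for H3K27ac and 0.894 for H3K4me1.

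In mouse the widest H3K4me3 peaks at a TSS lay at Tbx2 (10912 bp), a T-box repressor of the limb margins, and Wnt5a (10748 bp), a WNT ligand needed for limb outgrowth. They were followed by Prdm16 (9730 bp), Bahcc1 (9540 bp), a peak shared by Mab21l1 and Nbea (9242 bp), Irx5 (9146 bp), Bcl11a (8638 bp), Islr2 (8600 bp) and Brd2 (8452 bp). Tbx2 lies on chromosome 11 at 85832615 to 85841948 (GRCm38) and had H3K4me3 without H3K27ac or H3K4me1 at its TSS. In pig the widest lay at MN1 (5763 bp) and at TBX15 (5742 bp), a T-box factor of limb mesenchyme on chromosome 4 at 101918891 to 102032280 (Sscrofa11.1). NRP2 (5443 bp), BCORL1 (5272 bp), CD248 (5266 bp), a peak shared by NR2F2 and the uncharacterised LOC102160410 (4938 bp), a peak shared by IRX2 and C16H5orf38 (4852 bp), and SSBP3 (4850 bp) completed the 10 in pig. No gene stood among the first 10 in both species.

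The next question was which limb genes carried the marks at their TSS. Genes of the limb mesenchyme list, mostly transcription factors such as Tbx5, Hand2 and Shox2 but also the secreted kinase Pkdcc, were marked by H3K4me3 in 28 of 28 cases in mouse and 26 of 28 in pig, against 64.9% and 64.8% of other coding genes (Fisher's exact test, adjusted p = 0.000314 and 0.0150). H3K27ac lay at 26 of these 28 genes in mouse, against 41.5% of other genes (exact adjusted p = 1.80e-06), and at 21 of 28 in pig, against 46.6% (exact adjusted p = 0.0232). Hedgehog pathway genes carried H3K4me3 at 14 of 14 TSSs in both species (exact adjusted p = 0.0232 in each), and H3K27ac at 11 of 14 in mouse and 12 of 14 in pig (exact adjusted p = 0.0304 in each). Shh itself, the ligand, had H3K4me3 in both species and H3K27ac in neither. BMP signalling genes carried H3K27ac at 11 of 14 TSSs in mouse and 13 of 14 in pig (exact adjusted p = 0.0304 and 0.00999). For FGF signalling the count was 11 of 14 in mouse (exact adjusted p = 0.0304) and 9 of 14 in pig, which did not pass the test. WNT genes passed for H3K4me3 in mouse only (14 of 14, exact adjusted p = 0.0232), although pig had 13 of 14. Housekeeping genes, the positive control, had H3K27ac at 14 of 14 mouse and 12 of 13 pig genes (exact adjusted p = 0.000250 and 0.0150).

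These calls depended on the background. Of the 108 tests, 18 lay above and 6 below all other coding genes. Against orthologs only, a background added after the data were examined, 5 lay above and 16 below. The 5 were limb mesenchyme genes with H3K4me3 and H3K27ac in mouse (adjusted p = 0.0366 and 0.000243), BMP genes with H3K27ac in pig (0.0345), and housekeeping genes with H3K27ac in both species (0.00304 and 0.0469), by Fisher's exact test. Against orthologs only, the hedgehog calls ended, with adjusted p from 0.120 to 0.228, as did both limb mesenchyme calls in pig (0.217 for H3K4me3 and 0.203 for H3K27ac). At the 5' end of the gene alone, both of these (0.0604 and 0.259) and the hedgehog calls other than mouse H3K4me3 (0.0614 each) ended too. The BMP call in pig ended in the wider 50% of peaks (exact adjusted p = 0.0825, range 0.00875 to 0.0825 over 4 alternatives).

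**Figure D2:**
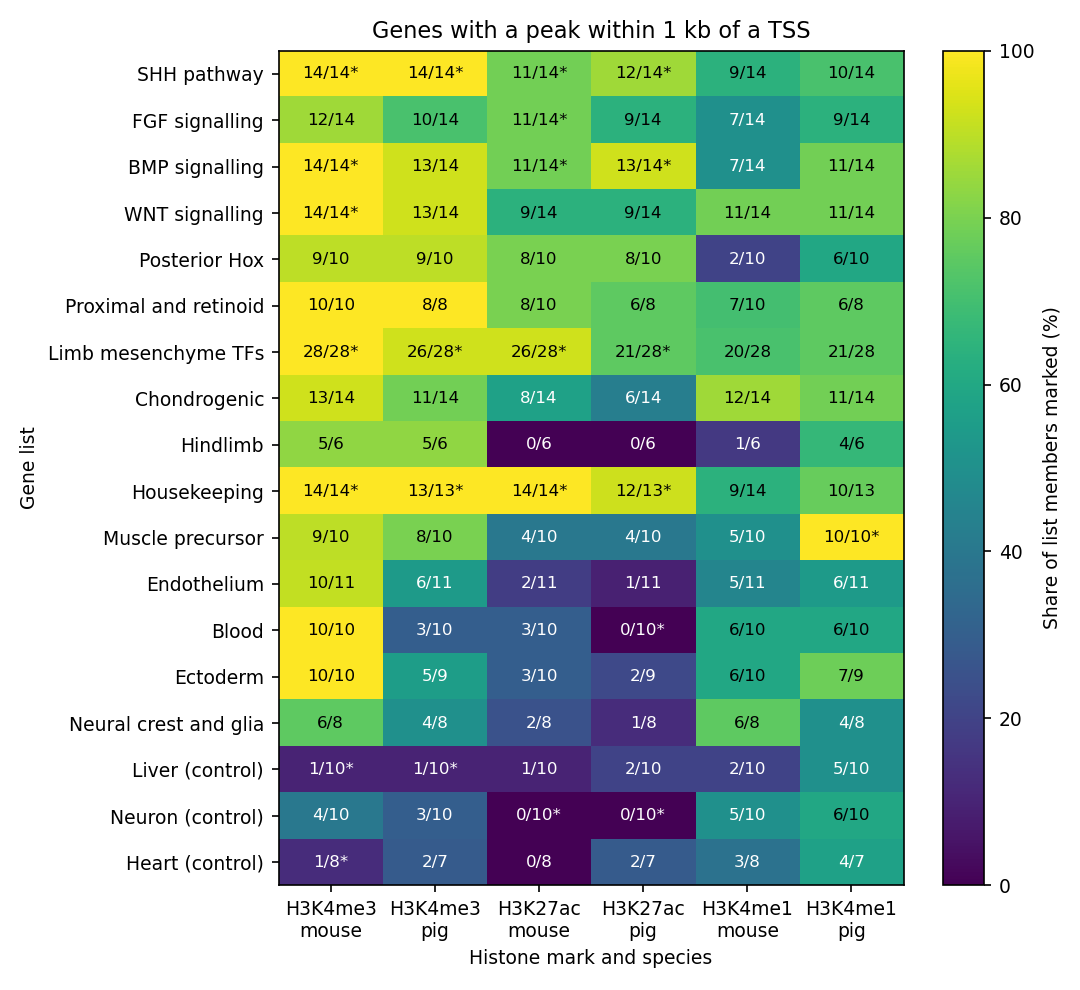
Share of genes marked within 1 kb of a TSS (colour, in percent) for 18 gene lists (rows) and each histone mark and species (columns), with the number marked out of the members annotated. Stars mark an adjusted p under 0.05 by Fisher's exact test against all other coding genes; limb mesenchyme genes with H3K27ac in mouse stood at 26 of 28.

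Lists for tissues outside the limb gave calls below the background, while those for other cell types of the forelimb gave 1 call above it and 1 below. Liver genes had H3K4me3 at 1 of 10 TSSs in each species, at Foxa3 (exact adjusted p = 0.00999 in each). Neuronal genes had no H3K27ac at 10 TSSs in either species (exact adjusted p = 0.0326 in mouse and 0.0232 in pig), and heart genes had H3K4me3 at 1 of 8 in mouse (exact adjusted p = 0.0232) and 2 of 7 in pig. In mouse the heart call ended in the wider 50% of peaks (exact adjusted p = 0.304) and with a 2.5 kb window (0.0585), over a range of 0.00116 to 0.304. The mouse neuronal call ended in the wider 50% of peaks (exact adjusted p = 0.172) and at the 5' end of the gene alone (0.0737), over a range of 0.00860 to 0.172. Blood genes, which include the erythroid factors Gata1 and Klf1, carried H3K4me3 at 10 of 10 TSSs in mouse and 3 of 10 in pig. H3K27ac lay at 3 of 10 blood genes in mouse and 0 of 10 in pig, and only the pig count passed the test (exact adjusted p = 0.0232). Endothelial genes had H3K4me3 at 10 of 11 in mouse and 6 of 11 in pig, with H3K27ac at 2 and 1. Ectodermal genes had it at 10 of 10 and 5 of 9, and genes of neural crest and glia at 6 of 8 and 4 of 8. Muscle precursor genes had H3K4me3 at 9 of 10 and 8 of 10, and H3K4me1 at 10 of 10 in pig (exact adjusted p = 0.0389), a call that ended in 3 of 4 alternatives (exact adjusted p from 0.0669 to 0.227).

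Hindlimb genes, including the hindlimb selectors Pitx1 and Tbx4, had H3K4me3 at 5 of 6 TSSs and H3K27ac at 0 of 6 in both species. With 6 genes the absence of H3K27ac did not pass the test against all coding genes (exact adjusted p = 0.124 in mouse and 0.100 in pig, Fisher's exact test). Against orthologs only it passed in pig (exact adjusted p = 0.0440). The Hox clusters are described for all Hox genes annotated in both species, which were chosen without the rule for named genes; Hoxc9, Hoxc10 and Hoxc11 are also 3 of the 6 hindlimb genes. Groups 9 to 13 of the HoxD cluster, which pattern the distal limb, had H3K27ac at 4 of 5 genes in both species and those of HoxA at 3 of 4 in both. Groups 9 to 13 of HoxC had H3K27ac at 0 of 5 in both species, with H3K4me3 at 4 of 5 in mouse and 3 of 5 in pig. HoxB groups 1 to 8 had H3K27ac at 5 of 7 genes in mouse and 0 of 7 in pig, with H3K4me3 at 7 and 3. These splits were not tested.

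The marking of orthologs was then compared between species. Of 14948 orthologs, 11157 carried H3K4me3 at the TSS in both, 1081 in mouse only, 465 in pig only and 2245 in neither, an odds ratio of 49.8 (95% interval 44.3 to 56.1). For H3K27ac, 6351 were marked in both, 1433 in mouse only and 1948 in pig only, an odds ratio of 11.9 (11.0 to 12.8). For H3K4me1, 8193, 2091 and 2611 were, with an odds ratio of 3.08 (2.86 to 3.32) and an adjusted p of 1.36e-189 by Fisher's exact test. The p-values for the other marks were too small to be computed. In the wider 50% of peaks the odds ratios were 4.75, 4.55 and 1.63, and at the 5' end of the gene alone that of H3K4me3 was 19.1. Genes marked in 1 species only were more often mouse genes for H3K4me3 (exact McNemar p = 1.21e-56) and pig genes for H3K27ac (p = 8.24e-19) and H3K4me1 (p = 3.55e-14). The pig lists also held more H3K27ac peaks, 27566 against 20875, and more H3K4me1 peaks, 103373 against 69962. These 2 splits therefore do not by themselves show more marking in pig. Genes are not independent replicates, and each p compares 1 list per species.

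Whether single lists leaned to 1 species could not be decided by the exact McNemar test. No list had more than 7 genes marked in 1 species only, and the smallest unadjusted p that 7 genes allow is 0.0156, so none of the 54 tests passed after adjustment. Blood genes with H3K4me3, 7 in mouse only and 0 in pig only, had an unadjusted p of 0.0156 and an adjusted p of 0.844, and theirs was the only unadjusted p under 0.05. In the test against all other orthologs marked in 1 species, also none of 54 passed, and limb mesenchyme genes with H3K27ac, 6 in mouse only and 1 in pig only, had an unadjusted Fisher's exact p of 0.0467.

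In the hedgehog, FGF, BMP, posterior Hox and limb mesenchyme lists, several genes with a mark in 1 species had a peak just outside the window in the other. Distances here are from the nearest annotated TSS of the gene to the nearest peak of the same mark. H3K4me3 was called in mouse only at Fgf10, the FGF ligand of limb bud mesenchyme, its receptor Fgfr2, Smad6, Hoxd11, Prrx1 and Alx4. The nearest pig H3K4me3 peak lay 1.69 kb from a TSS of Fgf10, 1.66 kb for Fgfr2, 2.68 kb for Smad6, 1.05 kb for Hoxd11 and 1.08 kb for Prrx1, but 29.4 kb for Alx4. In pig only it was called at Hoxa9, with a mouse peak at 1.42 kb. H3K27ac was called in mouse only at Sufu, Fgf10, Fgfr2, Smad6, Hoxa11, Irx3, Sall1, Prrx1, Alx4, Pax9 and Hic1. The nearest pig peak was 1.09 kb from a TSS for Sufu, 1.55 kb for Fgf10, 1.75 kb for Fgfr2, 3.58 kb for Smad6, 1.23 kb for Hoxa11, 1.02 kb for Irx3, 1.41 kb for Sall1 and 1.17 kb for Prrx1. It was 16.6 kb away for Alx4, 40.7 kb for Hic1 and 207 kb for Pax9, a paired-box factor. Genes with H3K27ac called in pig only included Hhip, Bmp5, Bmp7, Nog, Zbtb16 and Hoxa9. The nearest mouse peak was 79.0 kb from a TSS for Hhip, a hedgehog antagonist, while a mouse peak lay 0.607 kb from the gene body. For Bmp5 and Zbtb16 it was 10.2 and 50.5 kb from a TSS, and a mouse peak lay inside the gene. It was 21.8 kb from a TSS for Bmp7, 39.8 kb for the BMP antagonist Nog and 1.07 kb for Hoxa9. The other limb lists added genes that were chosen after their values were seen. H3K4me3 was called in mouse only at En1, Matn1, Hoxc11, Runx2 and Runx3, with the nearest pig peak 3.82, 3.58, 1.1, 53.5 and 65.8 kb from a TSS. A pig peak lay inside En1, Matn1, Hoxc11 and Runx2 and 2.01 kb from the gene body of Runx3. It was called in pig only at Ihh and Hoxc9, with the nearest mouse peak 94.1 and 3.58 kb from a TSS, and a mouse peak lay inside Hoxc9. H3K27ac was called in mouse only at En1, Matn1, Runx2 and Foxc1, whose TSSs lay 38.7, 8.90, 53.7 and 143.5 kb from a pig peak, and a pig peak lay inside Runx2. It was called in pig only at Rspo2 and Gdf5, whose TSSs lay 94.1 and 9.59 kb from a mouse peak, and a mouse peak lay inside Rspo2.

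Distal H3K27ac peaks gathered around hedgehog pathway genes in both species. The median member had 3.5 such peaks in mouse, where 95% of random lists matched on territory had 0 to 1 (adjusted permutation p = 0.00720), and 3 in pig, where random lists had 0 to 1.5 (adjusted permutation p = 0.0108). Gas1, a hedgehog co-receptor, had the most in both species, with 14 peaks in mouse and 21 in pig. Disp1 had 8 and 11, Cdon 6 and 8, Boc 5 and 8, and Gli3, a transcriptional repressor of the pathway in the limb, 5 and 17, which was second in pig. Such counts are not on a like scale in mouse and pig, since the median distal peak was 2604 bp wide in mouse and 891 bp in pig. By length covered, the order at Gas1 was reversed, with 52.9 kb in mouse and 21.3 kb in pig. FGF genes had a median of 4 peaks in pig against 0 to 1.5 in random lists (adjusted permutation p = 0.0120) and 1 in mouse (adjusted permutation p = 0.586). By the mean the FGF call in pig ended, at 4.36 against 1.57 in random lists (adjusted permutation p = 0.0576). Fgfr2 had 15 in pig and 3 in mouse, and Spry1, an inhibitor of FGF signalling, 10 and 2. In the wider 50% of peaks, the hedgehog call ended in mouse, at the 49.0th percentile of random lists, and the FGF call ended in pig (adjusted permutation p = 0.324, range 0.00103 to 0.324 over 6 alternatives). The hedgehog call in pig held in those 6 alternatives (adjusted permutation p from 0.00103 to 0.0115).

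The other limb lists did not pass this test. BMP genes had medians of 2 in mouse and 3 in pig (adjusted permutation p = 0.118 and 0.0984), led by Bambi with 5 and 14 peaks and Smad7 with 6 and 10. WNT genes had 1.5 and 3 (adjusted permutation p = 0.184 and 0.0984), with 3 peaks in mouse and 12 in pig at Wnt5a. Limb mesenchyme genes had 1 and 2 (adjusted permutation p = 1 and 0.140), with Pkdcc (6), Hand2 (5) and Twist1 (5) highest in mouse and Osr1 (17), Alx4 (11) and Msx2 (11) in pig. Chondrogenic genes had a median of 0.5 in mouse (adjusted permutation p = 1) and 2.5 in pig (adjusted permutation p = 0.0522). Their mean in mouse was 2.5 against 0.804 in random lists (adjusted permutation p = 0.00960), with 12 peaks at Sox5, 9 at Sox6 and 6 at Sox9, factors of early cartilage. Proximal and retinoid genes had 1 and 2 (adjusted permutation p = 0.543 and 0.323), with 13 peaks at Rarb in pig. Posterior Hox genes had 0 in both, where matched random lists averaged 0.0541 and 0.0570 peaks per gene, and hindlimb genes had 0 and 0.5. No other list passed; endothelial genes had medians of 0 and 1, with 8 and 18 peaks at Cdh5, the vascular cadherin.

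**Figure D3:**
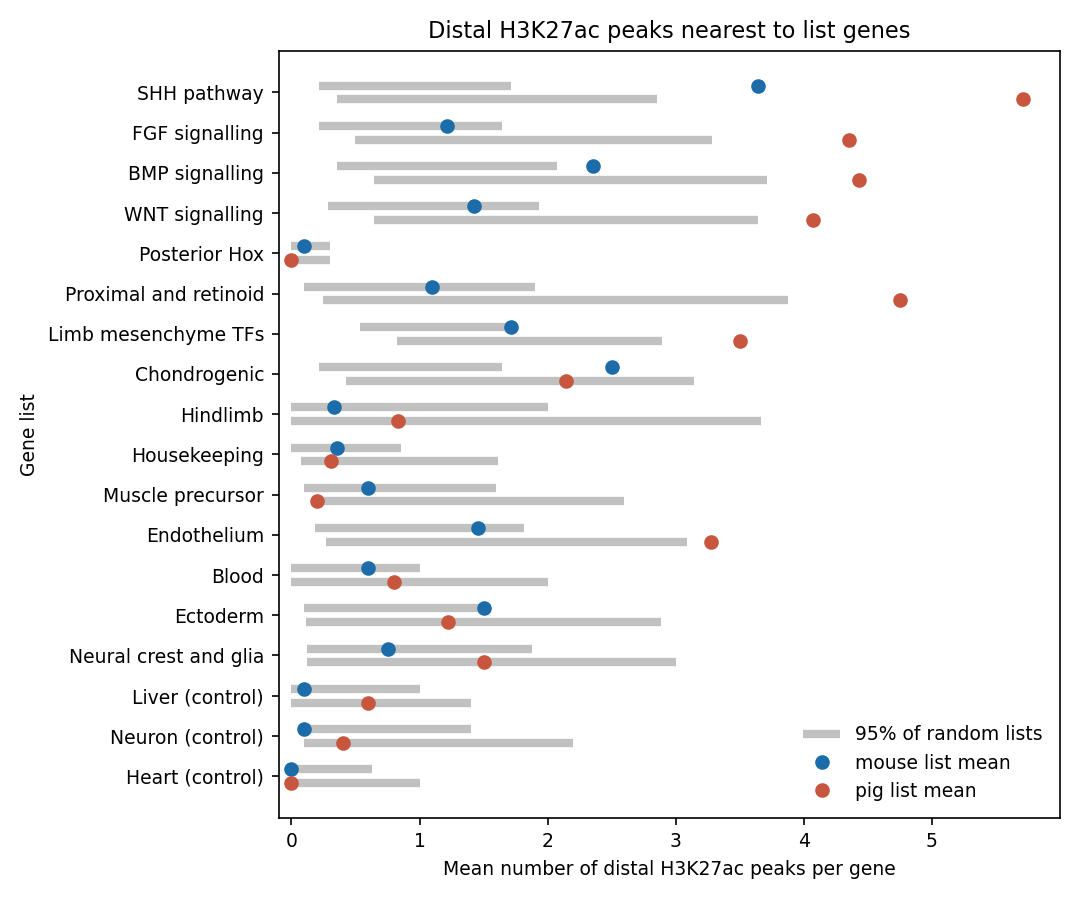
Mean number of distal H3K27ac peaks per gene (x axis) for 18 gene lists (y axis) in mouse (blue points) and pig (red points), with grey bars over 95% of random lists matched on territory. The hedgehog list stood at 3.64 in mouse and 5.71 in pig, where random lists averaged 0.842 and 1.36.

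Among all coding genes, Gas1 was also among the 10 with the most distal H3K27ac peaks in each species, as was Dcdc2c, with 16 peaks in mouse and 26 in pig. By length, the Dcdc2c peaks covered 47.6 kb in mouse and 22.5 kb in pig. Dcdc2c itself had neither H3K4me3 nor H3K27ac at its TSS in either species. The other 8 genes in mouse were Lyplal1 (13), Zfp521 (13), 4930558K02Rik (12), Map3k7 (12), Sox5 (12), 1500009L16Rik (11), Arhgap24 (11) and Noct (11). In pig they were SOX11 (32), ZFP36L1 (29), KIF26B (25), ETS1 (24), LDB2 (22), PALLD (22), DCLK1 (21) and BNC2 (19). Gas1 lies on mouse chromosome 13 at 60174405 to 60177535 on the minus strand (GRCm38) and on pig chromosome 10 at 28509168 to 28511554 on the plus strand (Sscrofa11.1). Within 500 kb on each side of its 5' end lay 28 H3K27ac peaks in mouse, 21 of them distal, and 33 in pig, 29 of them distal.

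**Figure D4:**
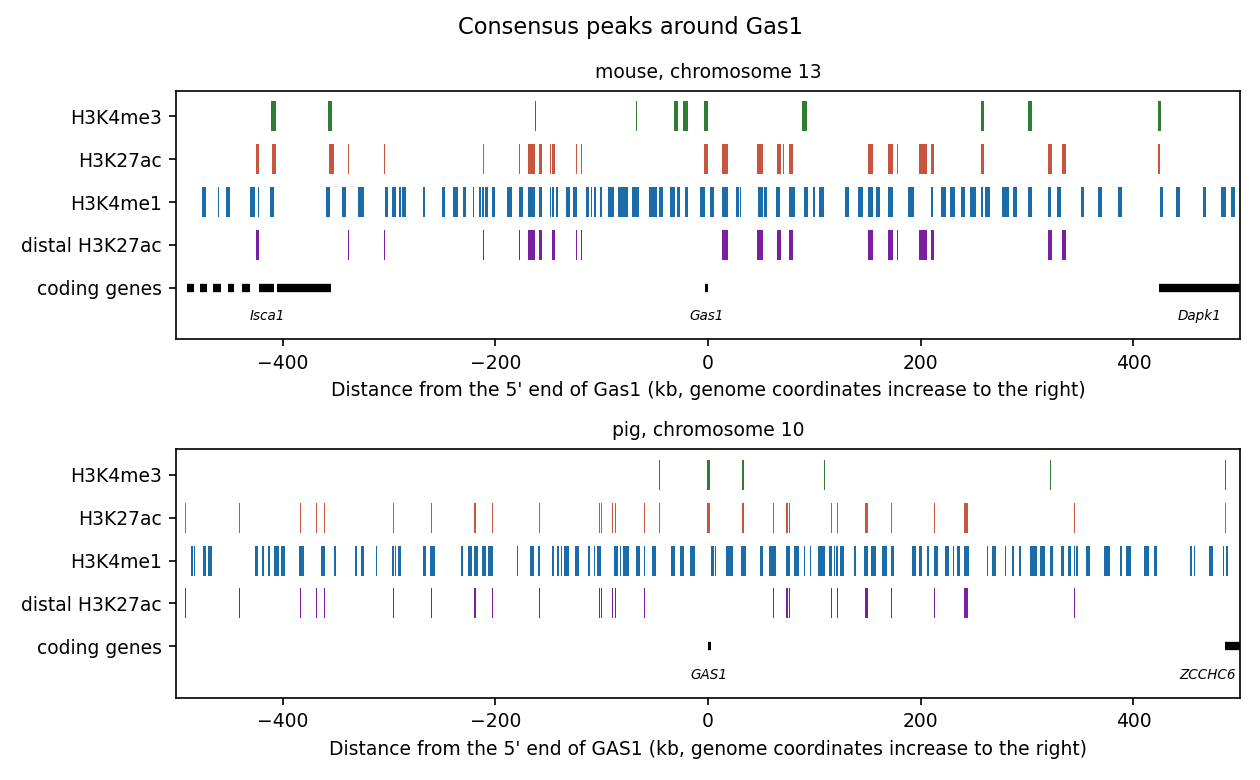
Peaks of each histone mark (rows, coloured boxes) within 500 kb of the 5' end of Gas1 (x axis, distance in kb) in mouse (upper panel) and pig (lower panel), with distal H3K27ac peaks in a separate row and coding genes in black, of which crowded names are left out. Very narrow peaks are drawn at a fixed smallest width; 21 distal H3K27ac peaks lay in the window in mouse and 29 in pig.

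Other genes had distal peaks in 1 species and none in the other. With at least 3 peaks in 1 species and 0 in the other, 182 orthologs were higher in mouse and 437 in pig. Pig had more distal peaks in all, 15795 against 10095, and narrower ones, so these numbers do not by themselves show more acetylation in pig. The largest differences toward mouse were at Slc10a7 (9 peaks), Inpp4b, Nucb2 and Slc39a11 (8 each) and Fer (7). Toward pig they were at Hes1, a Notch target, and Trio (17 each), Npvf (16), Pigc (14) and Cebpd (13). Territories differed for some of these, with 160 kb in mouse and 598 kb in pig for Trio. Across all 14948 orthologs, the numbers of distal peaks had a partial Spearman correlation of 0.206 (95% interval 0.190 to 0.222; permutation p = 0.0001, the smallest that 10000 permutations can give). Simulated peaks that shared only territory gave 0.135 in the same test. Both simulated sets used the territories of 21774 mouse genes, whereas real territories differ between species, so 0.135 is not a measured baseline here. Without partialling the observed value was 0.391. This is a correlation across genes, which are not independent replicates.

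The last comparison asked whether the DNA of mouse distal H3K27ac peaks was found again in marked pig chromatin. Of 10088 mouse peaks searched, 2730 (27.1%, 95% interval 26.2 to 27.9) matched a pig H3K27ac or H3K4me1 peak, against 1341 of 10088 control regions (13.3%, 12.6 to 14). The odds ratio was 2.42 (2.25 to 2.60; Fisher's exact test, two-sided, p = 4.52e-133). Of the 14 peaks around Gas1, 9 matched marked pig sequence and 7 matched it near the pig gene. Around Disp1, 4 of 8 peaks matched near the same gene, around Sox6 5 of 9 did and around Sox5 5 of 12 did. Around Fgfr2 0 of 3 matched. Matches near the same gene numbered 3 of 6 around Cdon, 2 of 5 around Gli3 and 1 of 5 around each of Boc and Bambi. They numbered 2 of 16 around Dcdc2c and 1 of 11 around Arhgap24. Over all regions searched, matches near the same gene were found for 16.2% of peaks and 4.32% of controls. Their odds ratio was 4.28 (3.84 to 4.78). Matches to pig H3K27ac peaks alone were rarer, at 6.0% of peaks and 1.41% of controls, with an odds ratio of 4.47 (3.71 to 5.38). Repeats took 36.0% of the control bases and 20.3% of the peak bases, so the controls held less sequence to search.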

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

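Mouse peaks on unplaced scaffolds, which no comparison used, numbered 17 for H3K4me3, 15 for H3K27ac and 4 for H3K4me1, each above the floor of 3 peaks set for flagging. Chosen only after the results were seen were the test of the sequencing batch, the limit on assembly gaps, the pooling of 5 cell type lists and the tests at those markers.

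Pig H3K4me3 and H3K27ac peaks were narrower than mouse peaks, at 0.508 and 0.398 of the mouse median. A difference in which genes were marked is argued against by the 11157 orthologs with H3K4me3 in both species, where the median pig to mouse width ratio was 0.556. For H3K4me1, whose pig libraries were sequenced at 100 bp like the mouse ones, the ratio was 0.894, so the sequencing batch may account for the narrower peaks. Batch and histone mark cannot be told apart, since no mark was sequenced both ways in pig. Pig H3K4me1 is also the list for which the design text states a single biological replicate, so replicate structure cannot be told apart from them either. A difference between the species stays open, as untested.

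Orthologs with H3K4me3 at the TSS in mouse only numbered 1081, against 465 in pig only. The split depended on the TSS window. Outside the 5 lists for other cell types it was 1062 and 464 with 1 kb, and 927 and 511 with 2.5 kb. Pig H3K4me3 peaks were also narrower, and whether their width lowered the pig count was not tested. Gaps in the pig assembly within 2 kb of the annotated pig 5' end are argued against. Of the 1081, all of which were examined, 0 had 100 or more unknown bases there. Read as a sample, a count of 0 would allow at most 0.278%. That limit replaced a planned odds ratio because the count was also 0 in the shared genes. The windows of all 14948 orthologs held 1 unknown base in total, so the count could not differ between groups. Gaps farther from the annotated 5' end were not examined. A misplaced TSS may account for part of the mouse-only orthologs, but the test could not single it out. Of the 1081, 60.4% had a pig H3K4me3 peak elsewhere in the gene or within 10 kb, against 34.7% of orthologs marked in neither species. The odds ratio was 2.87 (95% interval 2.47 to 3.34). Orthologs marked in neither species lacked H3K4me3 at the TSS in mouse too, so the groups compared also differed in mouse marking. Weak peaks stay open, with mouse peaks 0.940 as wide as at shared genes. Pooled markers of muscle precursors, endothelium, blood, ectoderm and neural crest were marked in mouse only at 19 of 48 orthologs and in pig only at 1 (exact McNemar p = 4.01e-05, unadjusted), and there neither a misplaced TSS (odds ratio 1.37, 0.548 to 3.42) nor weak peaks (width ratio 0.894) could be decided with 19 genes. A different share of these cell types in the dissected forelimbs is a candidate explanation that stays untested, since no value for cell composition was used here.

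Sequences of mouse distal H3K27ac peaks matched marked pig sequence more often than controls did. The mere presence of the sequence in the pig genome is argued against as the sole cause. Among regions of a sample with any match there, the best match lay in a marked region for 337 of 850 peaks (39.6%) and 102 of 752 controls (13.6%). The odds ratio was 4.19 (95% interval 3.26 to 5.38). Stronger conservation of the peaks stays open, because peaks and controls were not equalised in strength of match or in neighbourhood. With a stricter sequence match, the odds ratio over all regions rose from 2.42 to 3.38. Exons in the regions are argued against by the odds ratio of 2.56 (2.36 to 2.79) without them. The smaller repeat content of the peaks, 20.3% against 36.0%, is argued against as the whole account. In the sample, any match in the pig genome was found for 56.67% of peaks and 50.13% of controls. That odds ratio was 1.301 (1.127 to 1.502), against 2.42 (2.251 to 2.602) for a match to marked pig sequence. A part played by repeats stays open, since controls were not matched on them. No biological explanation was tested.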

How the results depend on the processing

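The background of orthologs only, territory in 20 bins, regions without exons and matches near the same gene were chosen only after the results were seen. No paired analysis was possible because each deposited list is a consensus over replicates, and leaving out a replicate was not possible for the same reason; with no score in the lists, the stricter threshold was the upper 50% by width, and the depth per sample is unknown. Tests of marking at the TSS above the background numbered 11 with the 5' end of the gene only and 5 against orthologs only, where 16 lay below it, compared with 18 and 6. With a 2.5 kb TSS window 26 lay above and 7 below, and in the wider 50% of peaks 19 and 4. Lists with more distal H3K27ac peaks than random lists numbered 3, against 1 in the wider 50% of peaks, 8 with H3K4me3 not considered, 5 by kilobases covered and 11 with random lists not matched. In the wider 50% of peaks the mouse hedgehog list fell to the 49.0th percentile of random lists, and 1 list differed in its split between species from other orthologs, compared with 0. The cause was not tested in these cases, except that unmatched random lists ignore territory. The overlap of marks (at least 2.53-fold), the odds ratios of shared marking (1.63 to 50.0), the correlation across species (0.183 to 0.391) and the odds ratio of the sequence match (2.42 to 4.47) kept their direction and stayed past the threshold under each alternative run.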

Other observations

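The pooling of the lists and both comparisons below were chosen only after the results were seen. Over the 9 limb lists, H3K4me3 lay in both species at 106 of 122 orthologs, in mouse only at 11 and in pig only at 3 (exact McNemar p = 0.0574). With a TSS window of 2.5 kb these counts were 112, 6 and 2 (exact McNemar p = 0.289). Over the 3 lists for liver, neurons and heart, with the 1 kb window, H3K4me3 lay in both at 3 of 27 orthologs, in mouse only at 3 and in pig only at 3 (exact McNemar p = 1). The split at the 5 lists for other cell types, 19 in mouse only and 1 in pig only, differed from that of all other orthologs, 1062 and 464 (Fisher's exact p = 0.0122, unadjusted), and with a TSS window of 2.5 kb the counts were 19 and 2 (p = 0.0110). Of the 11 limb genes marked in mouse only, 10 had a pig peak in the gene or within 10 kb, as did 8 of the 19 cell type markers (Fisher's exact p = 0.0182, unadjusted). The nearest pig H3K4me3 peak lay 143 kb from the gene body of Emcn, 121 kb from that of Tek, 40.2 kb for Pecam1 and 32.9 kb for Cdh5, all endothelial genes. Among blood genes marked in mouse only, a pig peak lay inside Spi1 and Runx1. The nearest was 1.23 kb from the gene body for Klf1, 11.2 kb for Gata1, 14.6 kb for Gfi1b, 58.9 kb for Csf1r, a receptor of macrophages, and 174 kb for Ptprc. The choice of these markers did not follow the rule for named genes.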
